A study of Mus musculus with 16 samples.

How the data were processed

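Fibroblasts (Epcam- CD45- CD31- gp38+) were sorted from the colons of 4 tamoxifen-treated Gli1CreERT2-ZsGreen mice into 4 populations by Sca1 and ZsGreen. Each of the 16 samples was amplified from 2 ng of RNA and hybridized to 1 Affymetrix array. The arrays were processed with Affymetrix Expression Console 1.1 per the submitters' processing notes. The summary method, background correction and normalization between arrays are not given in the sources used here.

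The deposited values are a score: each of the 45141 probe sets is standardized over the 16 arrays to mean 0 and SD 1, so a score carries neither level nor fold change. The design had assumed values that could be put on a log2 scale. The scores proved to be those of whole-number signals on a log scale, whose base cancels in standardizing. For each probe set the signals were therefore recovered in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, numba 0.67.0). Pairs of whole numbers up to 70000 (200000 in a second pass), with an SD over arrays of at most 4 log2 units, were tried for the 2 arrays with the closest scores. The smallest pair that put all other arrays within 0.0001 of a whole number was kept. All 45141 probe sets were recovered, with recomputed scores within 1e-09 of the deposited ones and signals from 58 to 155937. The recovery was tested on simulated data: 1000 of 1000 simulated probe sets on 16 simulated arrays were recovered exactly. No offset was needed before the log.

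Probe sets were named by the probe table of the platform: 28898 carried 1 gene, 551 several and 15588 none, and 104 were controls. Of those with 1 gene, 28689 had a gene identifier in the RefSeq table, and 0 symbols changed through it. Each of 17097 genes was represented by its probe set with the highest mean, 7180 genes having more than 1. Genes whose probe sets passed the threshold in opposite directions numbered 34 for reporter-high against Sca1+ reporter-negative cells, 53 and 5 for reporter-high and reporter-dim against Sca1- cells, and 0 in the other 3 comparisons with limma. Of 545 genes in 31 gene lists, written before the data were examined, 489 were measured. Ly6a was named by no probe set and is not analysed here.

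Array medians lay between 662 and 687. Several arrays had the same highest signal, 145621, so the signals appear to have been brought near a common distribution before they were standardized. The highest of 23 nonspecific controls was 234 to 488 per array, and 59.3% to 81.5% of probe sets lay above it. A gene at or below this highest control in all 4 arrays of a population is called at array background, and its difference is given as "at least" a fold, with the control signal in place of its own. Correlation of log2 signals between arrays of a population ran from 0.965 to 0.995. The ratio of 3' to 5' control signals moved with the populations: for Actb it was 1.24 ± 0.03 (SD, n = 4) in reporter-high, 1.15 ± 0.07 in reporter-dim, 1.11 ± 0.01 in Sca1+ reporter-negative and 1.11 ± 0.05 in Sca1- cells, and for Gapdh 0.997 ± 0.013, 1.02 ± 0.014, 0.954 ± 0.008 and 0.917 ± 0.017. Its effect on the differences was not tested. The labels take the 4 populations from the same animals. Deviations from the population mean correlated at 0.265 on average between arrays of the same mouse, with means per mouse from -0.0795 to 0.519, against -0.0893 between different mice. A check for mixed-up samples found that the arrays of 1 of the 4 mice did not match one another.

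Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) on log2 signals of all 16 arrays, with 1 mean per population and no block. The labels give the mouse of each array but no test or block, so the mouse was left out of the design and entered as a block in an alternative, which raised several counts more than 1.5 times. P values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The 6 comparisons were the 3 among Sca1+ populations, Sca1+ against Sca1- reporter-negative cells, and as secondary ones reporter-high and reporter-dim against Sca1- cells. A moderated F test covered the 4 populations together. Gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over lists. In counts over a list alone the adjustment covers its measured members. Counts of mice are of differences between the 2 arrays of each mouse. Figures were drawn with matplotlib 3.10.9.

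The sort genes are given first. Named genes are then the 5 largest rises and 5 largest falls of each of the first 4 comparisons, and 3 and 3 of the secondary ones. They had an adjusted p under 0.05, the same direction in all 4 mice and a higher population mean above the median of all probe sets. Sort genes and symbols of predicted genes (Gm, Rik, LOC), Mir, Snor and n-R5 were left out. From each list up to 3 members with the largest changes past the threshold follow. Genes named outside this rule are said to be so where they appear. The comparisons, lists, naming rule and the first set of alternatives below were fixed before the data were examined.

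Limma was tested on simulated data with the residuals of these arrays: 200 of 17097 genes were changed in 1 population, 10 times for each size and each of the first 4 comparisons. For reporter-high against Sca1+ reporter-negative cells it found 54.9%, 90.4% and 98.4% of genes changed by 0.5, 1 and 2 log2 units. For reporter-dim against Sca1+ reporter-negative cells it found 91.2% at 1 log2 unit and 98.8% at 2. For reporter-high against reporter-dim cells it found 57.2%, 89.7% and 98.3%, and for Sca1+ against Sca1- cells 51.6%, 92.4% and 98.6%. False calls averaged 0.2 to 69.5 per simulation with medians of at most 1, so that a few simulations held most of them. With 0 lists shifted among the 17097 genes, reporter-high against Sca1+ reporter-negative cells, camera with the preset correlation called at least 1 list in 49 of 50 simulations. With an estimated correlation it did so in 0 of 50. The chemokine and cytokine list, shifted by 1 log2 unit, was found in 50 of 50 with both. Its estimated correlation was 0.115, against 0.826 for the epithelial, 0.484 for the smooth muscle and 0.412 for the Hedgehog target list. Shifts of such lists were not simulated, so a call lost with an estimated correlation does not show that a list was unchanged. Calls with the preset correlation are therefore given beside those with an estimated one.

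The first set of alternatives was mouse as a block, only the 8 arrays compared, quantile normalization, centring on array medians, raising dim values to the 25th percentile, 2 filters on dim genes, the mean of a gene's probe sets, all probe sets, an intensity trend with robust variances, array weights, each array left out, a 2-fold limit, and divided control arrays. Alternatives chosen after seeing the data were the deposited scores without moderation, background subtraction (nonspecific control median, floor 16), scaling to 9 hybridization controls, the epithelial list mean as a covariate, each mouse left out, and a block with the mismatched mouse as 2 animals. An offset before the log was not run.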

Results

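Colon fibroblasts of tamoxifen-treated Gli1CreERT2-ZsGreen mice were sorted by the surface protein Sca1 and by the ZsGreen reporter. Gli1 is a transcription factor switched on by Hedgehog signalling. The label depends on tamoxifen given before the sort, so its brightness need not follow Gli1 activity at the time of sorting. The 4 populations were Sca1+ reporter-high, Sca1+ reporter-dim, Sca1+ reporter-negative and Sca1- reporter-negative cells, each measured on 1 array for each of 4 mice, 16 arrays in all. The number of arrays limits the precision. Differences are given as log2 ± SE between means of 4 arrays per population, from signals that hold the array background, so that differences of dim genes are too small. Adjusted p refers to 17097 genes unless a list is named. In a check for mixed-up samples the arrays of 1 of the 4 mice did not match one another, so counts of mice and values with mouse as a block rest on the labels.

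The sort genes served as a check of the labels. Gli1 read 2611 ± 321 (mean signal ± SD, n = 4) in reporter-high, 2323 ± 322 in reporter-dim, 1104 ± 299 in Sca1+ reporter-negative and 921 ± 318 in Sca1- cells. Pdpn, which encodes the gp38 protein used for the gate, read 7494 ± 1153, 6523 ± 759, 3833 ± 1125 and 2196 ± 1122 in the same order. Of the genes of the proteins gated out, Ptprc (CD45) read from 468 ± 150 in reporter-high to 900 ± 212 in Sca1- cells (log2 -0.97 ± 0.31 in reporter-high cells, adjusted p = 0.0238, lower in all 4 mice), Epcam 3472 ± 2370, 10281 ± 3827, 17885 ± 3522 and 17339 ± 5049, and Pecam1 (CD31) 969 ± 148, 2180 ± 962, 4065 ± 890 and 4149 ± 2048. The mean log2 signal of 18 colon epithelium genes was 11.66 ± 0.87 (SD), 13.28 ± 0.47, 13.98 ± 0.29 and 14.01 ± 0.44. Ly6a, the Sca1 gene, was named by no probe set in the table used. The first principal component held 63.7% of the variance and followed the mean of the colon epithelium list over the 16 arrays (r = 0.953, rho = 0.979, permutation p = 1e-04, the smallest 10000 permutations within mice can give). The second held 10.5% and followed the interstitial cell of Cajal list (r = 0.758, rho = 0.515, permutation p = 0.0032). The genes of both lists entered the components, and any list that differs between the populations can give a small permutation p. These values therefore do not single out the 2 cell types.

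**Figure D1:**
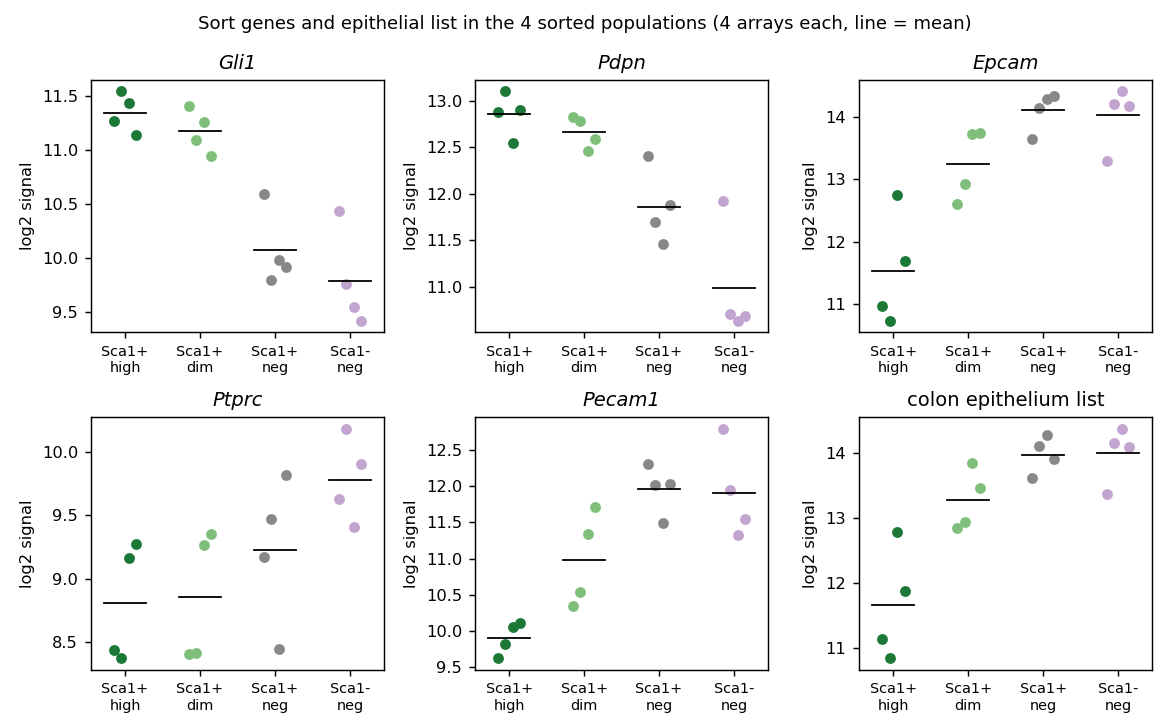
Signals of the sort genes and the mean of the colon epithelium list in each array. Epithelial signal rose from 11.66 in reporter-high to 14.01 in Sca1- cells (mean log2 of 4 arrays).

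Most measured Hedgehog targets and contractile genes were higher in reporter-high than in Sca1+ reporter-negative cells. As lists neither stayed called by camera with an estimated correlation (adjusted p = 0.601 for both). Fry called both (adjusted p = 0.0037 and 0.00783), as it did the colon epithelium list (0.00111). In the same comparison the colon epithelium list had a median of -2.40, and the 3' to 5' ratio of Actb was 1.24 against 1.11. Hhip, which encodes a Hedgehog-binding feedback inhibitor, was 3.08 ± 0.36 higher than in Sca1+ reporter-negative cells (15275 against 1804, adjusted p = 0.000132, higher in all 4 mice). Its level did not follow Gli1 over the populations. It read 5825 in Sca1- cells, where Gli1 was lowest, against 4473 in reporter-dim cells. The Notch ligand-like gene Dner rose by 3.29 ± 0.55, the smooth muscle actin Actg2 by 2.85 ± 0.44, the guidance cue Sema3a by 2.37 ± 0.33 and the growth factor Bmp6 by 2.10 ± 0.21. Of 13 measured Hedgehog targets 9 rose, 1 fell and 3 did not pass, with Foxf2 at 1.66 ± 0.39 and Osr1 at 1.63 ± 0.25. Of 16 smooth muscle and myofibroblast genes 11 rose, among them the myosin Myh11 at 1.64 ± 0.32, and 5 did not pass. The mean of this list rose by 0.56 ± 0.59 (SD, n = 4) more than that of the adventitial list below, in 3 of 4 mice (lowest -0.25). Of 18 genes of Hedgehog signal transduction 9 rose and 2 fell: the effector Gli2 rose by 1.43 ± 0.22, and the ligand Ihh, made by epithelium in the colon, fell by 1.36 ± 0.25.

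Part of the matrix and growth factor genes of fibroblasts also rose between these populations, and others did not pass or fell. Of 24 fibrillar collagen and elastic fibre genes 13 rose (14 adjusted over the list alone) and 0 fell, led by the elastin gene Eln (1.32 ± 0.24) and the crosslinking enzyme Loxl2 (1.20 ± 0.28). Of 20 basement membrane genes 12 rose, such as Col4a6 (1.35 ± 0.40), and 2 fell, the epithelial laminins Lamb3 (-2.41 ± 0.38) and Lama3 (-1.90 ± 0.25). Among niche signals for epithelium, 4 of 9 BMP ligands rose (6 over the list alone), Bmp4 by 1.35 ± 0.30, and 1 fell; 6 of 12 BMP antagonists rose, Grem1 by 1.65 ± 0.34, and 2 fell, Bmper by 2.20 ± 0.36. Of 25 Wnt ligands and R-spondins 7 rose and 1 fell, with Wnt5b at 1.42 ± 0.21, Wnt2b at 1.31 ± 0.16 and Wnt4 at 1.14 ± 0.17, while the list's median was -0.02 and its mean 0.25. Camera did not call the Wnt ligands (adjusted p = 0.301), the BMP antagonists (0.169) or the growth factors (0.0886) with the preset correlation. The growth factor list had 10 of 21 higher and 3 lower (11 and 4 over the list alone), with Vegfc at 1.64 ± 0.35 and Hbegf at -2.53 ± 0.37. Of 21 markers of CD34+ Sca1+ adventitial fibroblasts 13 rose (16 over the list alone), Ackr4 by 1.78 ± 0.43, and 2 fell, the peptidase Dpp4 by 2.00 ± 0.37. With the epithelial list mean as a covariate both turned, to -0.52 for Ackr4 and 0.075 for Dpp4. Of 20 PDGFRA-high subepithelial markers 8 rose (11 over the list alone) and 2 fell.

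Among the genes lower in reporter-high cells were those of other cell types and of proliferation. All 18 measured colon epithelium genes fell, for instance the cadherin Cdh1 by 2.77 ± 0.43 (3659 against 24975) and the goblet cell gene Agr2 by 2.89 ± 0.45, with a list median of -2.40. The 5 largest falls outside that list were Perp (-3.49 ± 0.47), Kcnk1 (-3.39 ± 0.64), Hao2 (-3.37 ± 0.39), Pof1b (-3.36 ± 0.32) and the claudin Cldn23 (-3.35 ± 0.47). With the epithelial list mean as a covariate Kcnk1 turned to 0.35, and Krt7 below to 0.16. Of 29 proliferation genes 22 fell (24 over the list alone) and 0 rose, Mki67 by 2.00 ± 0.35. With the epithelial covariate Top2a of this list turned to 0.44, and Mki67 kept its direction. Of 19 endothelial genes 10 fell and 1 rose (11 and 1 over the list alone), of 18 leukocyte genes 6 fell (7 over the list alone), such as Jchain (-2.62 ± 0.57), and of 12 mesothelial genes 6 fell, the keratin Krt7 by 2.38 ± 0.43. The whole comparison called 5276 genes, 2900 higher and 2376 lower, and 441 and 789 of them passed a 2-fold limit. Without mouse 2 or mouse 4 it called 2734 and 3194.

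Camera with a preset correlation of 0.01 called 13 of 31 lists between reporter-high and Sca1+ reporter-negative cells, among them the colon epithelium list (adjusted p = 9.23e-13), the collagens (0.000241), smooth muscle (0.000272) and the Hedgehog targets (0.00039). With an estimated correlation none of the 13 stayed called: the adjusted p was 0.601 for 12 of them and 0.604 for the PDGFRA-high list. With the mean of the epithelial genes as a covariate, limma called 1 gene (1526 at an unadjusted p under 0.05), and the covariate and the contrast moved together across arrays. Scaling the arrays to their hybridization controls raised the all-gene median by 0.38 and called 11815 genes, 92.5% of them higher against 55.0% in the main analysis. Under this scaling the median of the leukocyte list turned from -0.24 to 0.15 and that of the mesothelial list from -0.31 to 0.07, and the colon epithelium list kept all 18 falls.

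Other lists held genes that moved in both directions or few that passed. Of 13 secreted Wnt inhibitors 3 rose, Dkk3 by 1.29 ± 0.25, and 1 fell; of 13 canonical Wnt response genes 2 rose and 1 fell; of 8 BMP response genes 2 rose and 2 fell, Id1 by 1.12 ± 0.17. The interferon list had 4 of 21 higher and 1 lower, antigen presentation 1 of 10 higher, complement 4 of 14 higher and 2 lower, and retinoid handling 5 of 14 higher and 1 lower (2 over the list alone), with the retinol dehydrogenase Adh1 at -1.30 ± 0.19. Of 24 immediate early and dissociation genes 3 rose and 2 fell, of 20 matrix proteases 7 rose and 2 fell, of 14 lamina propria markers 6 rose and 2 fell (7 and 3 over the list alone), and of 13 reticular cell markers 4 rose (5 over the list alone) and 1 fell. Pericyte markers had 3 of 14 higher and 2 lower, and 2 of 12 glial and neuronal genes rose and 1 fell. Chemokines had 5 of 32 higher and 3 lower (2 and 3 over the list alone).

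Reporter-dim and reporter-high cells had 253 shared calls against Sca1+ reporter-negative cells. Both comparisons use the same 4 control arrays, which raises the overlap. With these arrays divided, 60.5 genes were shared on average (13 to 195). The number of shared calls fell to 1 with the epithelial list mean as a covariate and to 10 without mouse 2 or mouse 4, and rose with mouse as a block. Of the genes called in both, 122 of 153 higher and 61 of 100 lower ones changed less in reporter-dim cells. The other 31 and 39 changed more, Ptx3 among them. The contractile part of the reporter-high differences was not called in reporter-dim cells, with 0 of 16 smooth muscle genes past the threshold with limma (1 rose at an unadjusted p under 0.05, 1 over the list alone). With mouse as a block 1 rose, Hhip at 1.31 ± 0.36 without the block (adjusted p = 0.0745, and 0.0278 with it, higher in all 4 mice). Against Sca1+ reporter-negative cells Dner rose by 2.53 ± 0.55, Bmp6 by 1.70 ± 0.21, the matrix link protein Hapln1 by 1.66 ± 0.31, the YAP target Ccn2 by 1.63 ± 0.36 and Aard by 1.57 ± 0.30. The pentraxin Ptx3, an acute-phase opsonin, fell by 2.69 ± 0.31 (890 against 5749, adjusted p = 0.00158, lower in all 4 mice), followed by Adam12 (-1.74 ± 0.23), Saa3 (-1.63 ± 0.30) and Cyp1b1 (-1.61 ± 0.22). The BMP modulator Bmper was at array background in reporter-dim cells and at least 3.20-fold lower there, and the mesothelial factor Wt1 at least 2.19-fold lower. Of the 13 Hedgehog targets 3 rose (9 over the list alone), Gli1 among them, with Osr1 at 1.21 ± 0.25 and Sfrp1 at 1.04 ± 0.22, and 0 fell (1 over the list alone). With mouse as a block 9 rose and 1 fell. Of 18 genes of Hedgehog signal transduction 0 rose and 2 fell (5 and 3 over the list alone), Cdon by 0.80 ± 0.10 and Gas1 by 0.46 ± 0.11. Of 9 BMP ligands 1 rose and 1 fell (3 and 2 over the list alone), Gdf10 by 1.12 ± 0.24. Wnt2b rose by 1.22 ± 0.16, Wnt5b by 0.95 ± 0.21 and Wnt4 by 0.89 ± 0.17, within 4 rises and 1 fall among 25 Wnt ligands and R-spondins. The growth factor Hgf rose by 1.20 ± 0.25. With limma 0 of the 18 epithelial genes passed (5 fell at an unadjusted p under 0.05, list median -0.67), and 8 fell with mouse as a block.

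In this comparison 258 genes were called, 154 higher and 104 lower, and 2386 with mouse as a block, of which 44.3% were higher against 59.7% without it. With the epithelial list mean as a covariate it called 39. Without mouse 1, 2, 3 or 4 it called 1540, 10, 33 and 10. The count depended on single arrays: it was 37, 34 and 154 without the reporter-dim array of mouse 1, 2 or 4, 43, 35 and 36 without the reporter-negative array of mouse 2, 3 or 4, and 1258 without that of mouse 1. Arrays outside the comparison, which enter through the shared spread, moved it too: it was 93, 113 and 96 without the reporter-high array of mouse 1, 2 or 4, and 1340 without the Sca1- array of mouse 1. Scaling to the hybridization controls gave 473 calls, 90.3% of them higher. Camera called 8 lists, including proliferation (adjusted p = 1.41e-07; 0 of 29 fell with limma, 15 at an unadjusted p under 0.05, 7 over the list alone), the collagens (1.48e-06; 2 of 24 rose, 7 over the list alone), the adventitial list (0.000279; 1 rose and 1 fell, 11 and 2 over the list alone), basement membrane (0.000279; 0 passed, 11 rose and 2 fell at an unadjusted p under 0.05, 6 rose and 1 fell over the list alone) and mesothelium (0.000181; 2 of 12 fell, 5 over the list alone). With an estimated correlation the adjusted p was 0.399 for mesothelium and 0.724 for the other 7. With mouse as a block 12 proliferation and 3 mesothelial genes fell, and 11 collagens rose. In the same fit 10 adventitial genes rose and 2 fell, and 6 basement membrane genes rose and 2 fell.

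The reporter-high and reporter-dim comparisons, which share their 4 control arrays, called 253 genes in the same direction, 153 higher and 100 lower, and 0 in opposite directions. Independent lists of these sizes would share 26.1 higher and 14.5 lower, a value that leaves out the shared control arrays. Groups simulated without change shared at most 0 genes in 100 simulations with limma. A simulation without change is built to call few genes, so this count says little about the overlap. The fold changes correlated across genes at 0.905, against 0.447 simulated, with a covariance of 0.152 against 0.0115, a difference of 0.140. With the control arrays divided 2 and 2 over 6 divisions, 60.5 genes were shared on average (13 to 195), at a correlation of 0.777 and a covariance of 0.138. With mouse as a block 2305 were shared. With the epithelial list mean as a covariate 1 was shared, without mouse 2 or mouse 4 10 each, without mouse 3 33, and without mouse 1 more than 253. The epithelial list mean was 13.98 in Sca1+ reporter-negative, 13.28 in reporter-dim and 11.66 in reporter-high cells. Without 1 array the number ran from 34 to 1298: it was 37, 34 and 151 without the reporter-dim array of mouse 1, 2 or 4, 89, 107 and 93 without the reporter-high array of mouse 1, 2 or 4, 41, 35 and 36 without the Sca1+ reporter-negative array of mouse 2, 3 or 4, 1221 without that of mouse 1, and 1298 without the Sca1- array of mouse 1.

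Reporter-high and reporter-dim cells differed in contractile and epithelial genes and little in Gli1 (0.17 ± 0.21, adjusted p = 0.73). As lists neither stayed called by camera with an estimated correlation (adjusted p = 0.789 for smooth muscle and 0.631 for epithelium). The 3' to 5' ratio of Actb was 1.24 against 1.15, and that of Gapdh 0.997 against 1.02. Actg2 rose by 2.27 ± 0.44 (8057 against 1672), the integrin Itga8, which anchors smooth muscle to matrix, by 1.79 ± 0.29, Speer4b by 1.81 ± 0.35 and Hhip by 1.77 ± 0.36. The cardiac actin Actc1 was at array background in reporter-dim cells and at least 2.43-fold higher in reporter-high cells. Of 16 smooth muscle genes 4 rose (10 over the list alone), with Cnn1 at 1.32 ± 0.23, and 0 fell, at a mean shift of 0.77 ± 0.13 (SD over 4 mice, higher in all 4). The Hedgehog pathway repressor Sufu rose by 0.54 ± 0.08. Of 21 growth factors 1 rose, Pdgfc by 1.37 ± 0.26, and 1 fell, Hbegf by 1.75 ± 0.37 (3 and 1 over the list alone). Of 18 epithelial genes 9 fell (18 over the list alone), Fabp2 by 2.14 ± 0.40, and the largest falls were Hao2 (-2.61 ± 0.39), Perp (-2.51 ± 0.47), Cldn23 (-2.43 ± 0.47), the water channel Aqp4 (-2.41 ± 0.39) and Pof1b (-2.38 ± 0.32).

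This comparison called 242 genes, 83 higher and 159 lower, and 1280 with mouse as a block. With limma it called 0 with the epithelial list mean as a covariate (1458 at an unadjusted p under 0.05), 0 without mouse 2 (2096 unadjusted) and 0 without mouse 4 (2006 unadjusted), and 620 without mouse 1. The count was 9, 10 and 69 without the reporter-high array of mouse 1, 2 or 4, 523 without that of mouse 3, 2 without the reporter-dim array of mouse 4, and 0 with limma without that of mouse 3 (2160 at an unadjusted p under 0.05). Without arrays outside the comparison it was 833 (Sca1- array of mouse 1) and 153 (Sca1+ reporter-negative array of mouse 2). Scaling to the hybridization controls raised the median of all genes by 0.35 and gave 9929 calls, 97.3% of them higher against 34.3% without it, and the medians of the endothelial and leukocyte lists turned from -0.26 to 0.08 and from -0.11 to 0.23. Camera called 8 lists, epithelium lower (adjusted p = 3.52e-20) and smooth muscle higher (1.33e-05) at the head, with 0.631 and 0.789 for these with an estimated correlation, and at least 0.789 for the other 6.

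**Figure D2:**
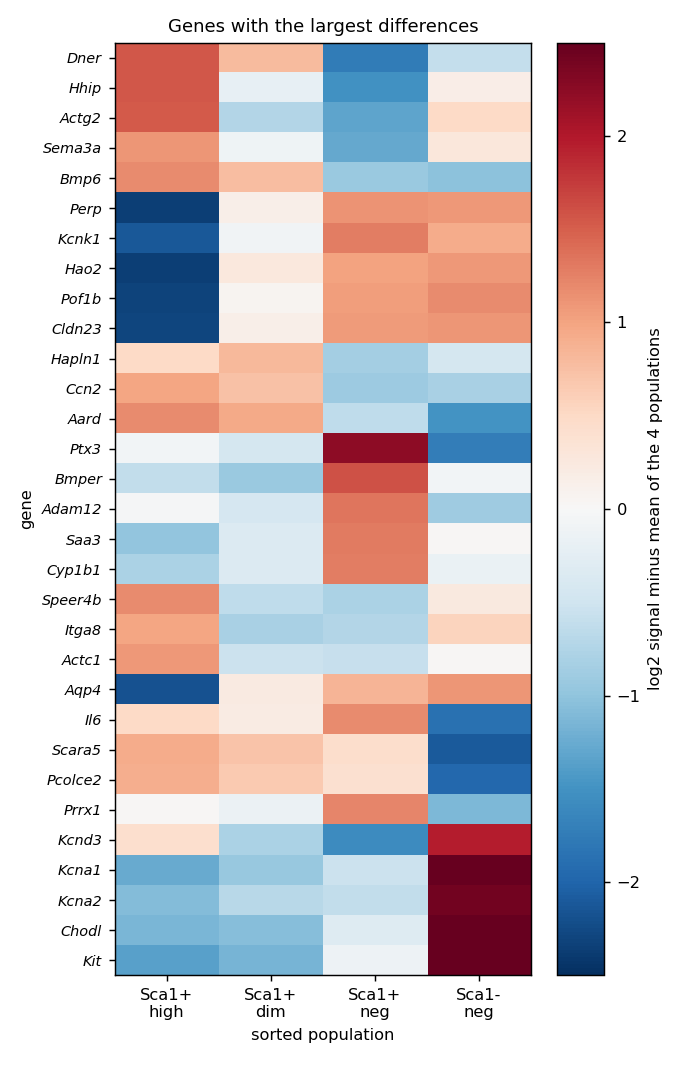
Mean log2 signal of the genes with the largest differences, relative to the mean of the 4 populations. Hhip is 3.08 higher in reporter-high than in Sca1+ reporter-negative cells, and Kit 2.78 lower in Sca1+ than in Sca1- reporter-negative cells.

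Among reporter-negative cells, adventitial markers, chemokines and cytokines were higher in Sca1+ cells, and genes of interstitial cells of Cajal, the pacemaker cells of the gut, were higher in Sca1- cells. Ptx3 was 3.97 ± 0.31 higher in Sca1+ cells (5749 against 366, adjusted p = 4.93e-06, higher in all 4 mice), the cytokine Il6 3.05 ± 0.53, the ferritin receptor Scara5 2.55 ± 0.29, the procollagen enhancer Pcolce2 2.38 ± 0.18 and the mesenchymal transcription factor Prrx1 2.34 ± 0.30. Kit, the receptor that interstitial cells of Cajal need, was 2.78 ± 0.23 lower in Sca1+ cells (535 against 3669), together with the potassium channels Kcnd3 (-3.55 ± 0.41) and Kcna1 (-3.26 ± 0.30), and Chodl (-2.85 ± 0.26). Kcna2 was at array background in Sca1+ cells and at least 6.77-fold lower. All 5 measured genes of the interstitial cell of Cajal list fell, with Prkcq at -2.42 ± 0.14 and Etv1 at -1.46 ± 0.25. Of 12 glial and neuronal genes 5 fell, Gfap by 1.53 ± 0.26 and Fabp7 by 1.55 ± 0.22, with S100b at least 1.94-fold lower.

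Of 21 adventitial markers 12 rose in Sca1+ cells (15 over the list alone) and 0 fell, with Ebf2 at 1.58 ± 0.19 and Ly6c1 at 1.53 ± 0.25. Of 32 chemokines and cytokines 12 rose (19 over the list alone) and 0 fell (1 over the list alone), with the alarmin Il33 at 1.93 ± 0.36 and the neutrophil attractant Cxcl1 at 1.79 ± 0.31. Matrix proteases and inhibitors had 9 of 20 higher (13 over the list alone), Adam12 at 2.21 ± 0.23 and Adamts5 at 1.88 ± 0.30, complement 4 of 14 (8 and 1 lower over the list alone), C2 at 1.21 ± 0.12, and growth factors 3 of 21 higher and 1 lower (8 and 1 over the list alone), the lymphangiogenic Vegfd at 1.87 ± 0.22. The retinoid enzyme Aldh1a2 was the 1 rise among 14 retinoid genes (1.71 ± 0.26). Fibrillar collagens had 4 rises and 1 fall (12 and 1 over the list alone), Efemp1 at 1.71 ± 0.28, and the 25 Wnt ligands and R-spondins 3 rises, Wnt5a at 1.15 ± 0.28. Other rises were 4 of 20 PDGFRA-high markers (6 over the list alone, with 1 fall), 4 of 14 lamina propria markers (7 over the list alone), 2 of 13 reticular cell markers (4 over the list alone) and 3 of 24 immediate early genes (4 over the list alone). Smooth muscle had 3 of 16 lower (6 over the list alone), Pcp4 by -2.30 ± 0.32 and Actg2 by -1.81 ± 0.44, and pericyte markers 4 lower and 2 higher of 14 (7 and 3 over the list alone), Rgs5 by -2.18 ± 0.29. Hhip, in the smooth muscle and Hedgehog target lists, was 1.69 ± 0.36 lower in Sca1+ cells (1804 against 5825, adjusted p = 0.0188). It was the 1 of 13 Hedgehog targets past the threshold. Of the epithelial genes 0 of 18 passed with limma, and 0 at an unadjusted p under 0.05, Epcam at 0.08 ± 0.39.

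The comparison by Sca1 called 419 genes, 209 higher and 210 lower, 635 with mouse as a block, 789 without the Sca1- array of mouse 1 and 265 without that of mouse 4. It was 155, 228 and 133 without mouse 2, 3 or 4, and 626 with the epithelial covariate. Scaling to the hybridization controls left 440 calls, with 65.0% of them higher against 49.9%. Camera called 16 lists, the strongest being the adventitial list (adjusted p = 7.22e-21), interstitial cells of Cajal (8.36e-15), matrix proteases (7.33e-15) and chemokines (1.97e-13). With an estimated correlation 4 stayed called: interstitial cells of Cajal at 0.0035, and chemokines, the adventitial list and glia at 0.0147. These 4 were the only calls that held with an estimated correlation over the 4 main comparisons, where 45 were made with the preset one. Of the 12 lost, the growth factors stood at 0.0742, matrix proteases at 0.0789, complement and the immediate early list at 0.101, retinoid handling at 0.166, reticular cell markers at 0.192, pericyte markers at 0.214, PDGFRA-high markers at 0.223, lamina propria markers at 0.231, and collagens, smooth muscle and Wnt ligands at 0.24 with an estimated correlation. In arrays simulated without any list shifted (17097 genes, reporter-high against Sca1+ reporter-negative), camera called 9.52 of 31 lists on average with the preset correlation and 0 in 50 simulations with an estimated one. Fry, which asks whether the members of a list move together whatever other genes do, called 32 over the 4 comparisons.

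**Figure D3:**
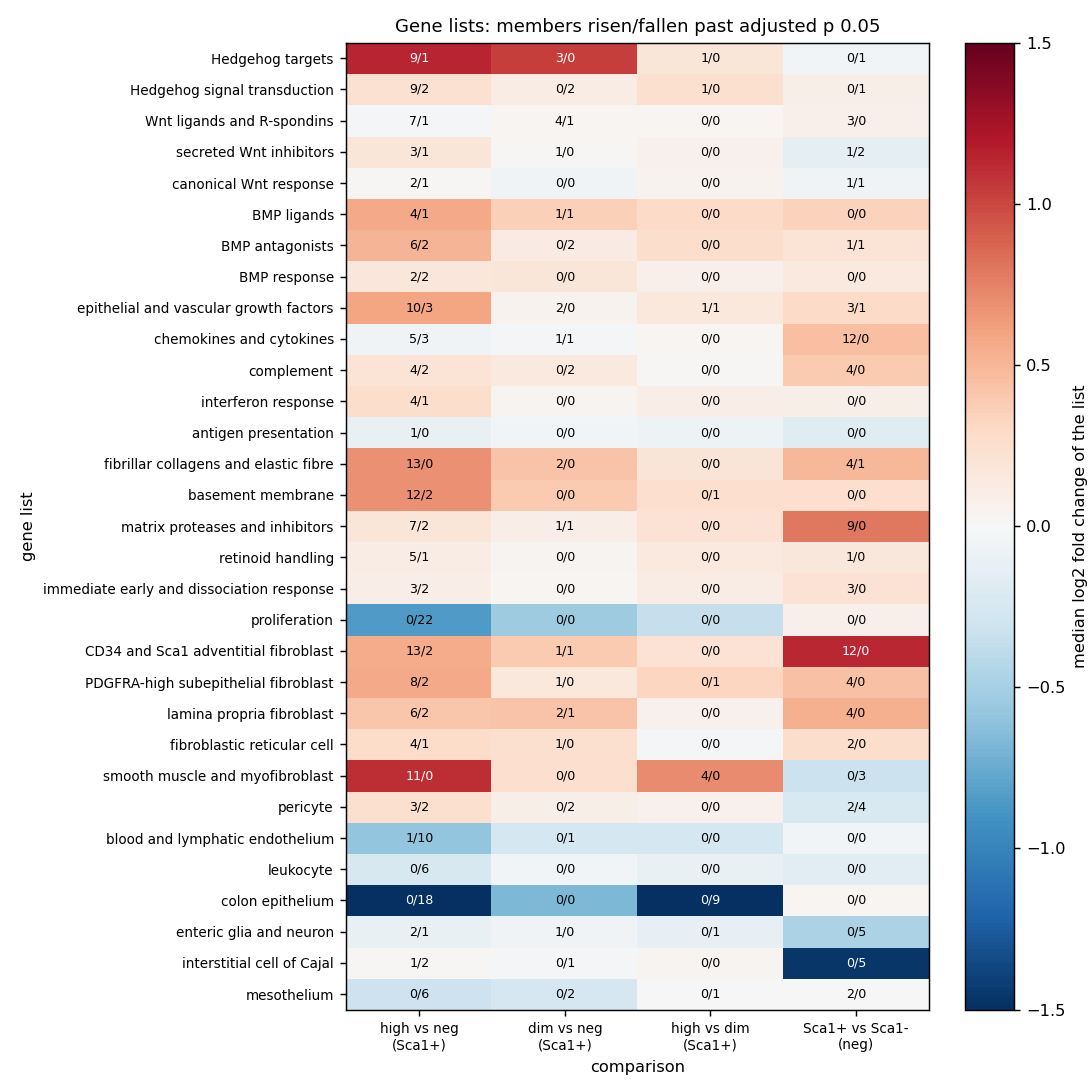
Median log2 fold change of 31 gene lists in 4 comparisons, with the numbers of members that rose and fell. The colon epithelium list fell by 2.40 between reporter-high and Sca1+ reporter-negative cells, and the interstitial cell of Cajal list by 1.46 between Sca1+ and Sca1- cells.

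Both reporter-positive populations differed from Sca1- cells in both sort markers. Scara5 was 3.04 ± 0.29 higher in reporter-high and 2.82 ± 0.29 higher in reporter-dim cells, Pcolce2 2.87 ± 0.18 and 2.63 ± 0.18, the hyaluronan synthase Has2 2.83 ± 0.38 higher in reporter-high cells and the Wnt modulator Sfrp2 2.65 ± 0.36 higher in reporter-dim cells. Kit fell (-4.00 ± 0.23 and -3.81 ± 0.23), as did Kcna1 (-3.98 ± 0.30 and -3.67 ± 0.30) and Chodl (-3.68 ± 0.26 and -3.60 ± 0.26). Of 24 fibrillar collagen genes 20 rose and 1 fell in reporter-high cells, and 19 rose and 1 fell in reporter-dim cells (20 and 1 over the list alone). In the same comparisons genes of other cell types fell: 18 of 18 epithelial genes in reporter-high cells (list median -2.36) and 1 in reporter-dim cells (list median -0.75, 0 over the list alone and 5 at an unadjusted p under 0.05 with limma). Of 19 endothelial genes 14 and 3 fell, with 1 rise in each (over the list alone 15 fell and 2 rose in reporter-high cells, and 10 fell and 1 rose in reporter-dim cells), and of 18 leukocyte genes 9 and 2 (10 and 5 over the list alone). The counts were 6143 genes for reporter-high cells, 3283 higher and 2860 lower, and 2368 for reporter-dim cells, 1361 higher and 1007 lower (3769 with mouse as a block). With the epithelial list mean as a covariate they fell to 168 and 1287, without mouse 2 to 3838 and 614, without mouse 3 the dim count to 1529, and without mouse 4 to 4349 and 789. The dim count was 1409 and 1506 without the reporter-dim array of mouse 1 or 2, 4025, 1542 and 1435 without the Sca1- array of mouse 1, 2 or 4. Scaling to the hybridization controls raised the medians of all genes by 0.46 and 0.12, with 93.1% and 86.4% of calls higher against 53.4% and 57.5%, and turned the medians of 2 lists in reporter-high cells, leukocyte from -0.40 to 0.07 and mesothelium from -0.19 to 0.28. Camera called 21 and 24 lists, of which 0 and 1 held with an estimated correlation, the interstitial cell of Cajal list in reporter-dim cells at 0.0435. The adjusted p of the lists lost with an estimated correlation was at least 0.259 in reporter-high and 0.0731 in reporter-dim cells.

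Across the 4 populations together 5522 of 17097 genes differed by the moderated F test.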

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

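In this part the slopes on the epithelial list and the regroupings of samples were planned before their results were seen; the slopes on the 3 other cell lists were chosen after the pattern they address was seen but before their own results, and all other tests after their results.

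Most genes lower in reporter-high than in Sca1+ reporter-negative cells rose with the epithelial list mean within populations. For these genes no slopes were run on the other lists that fell, so the slopes do not single out epithelium. Of 2358 such genes outside the epithelial list, 91.0% rose with the epithelial list mean among arrays of the same population, against 55.1% of 11821 genes not called and 10.1% of 2900 higher genes (87.6 to 92.2% with any 1 array left out). Scaling to the hybridization controls left 37.5% of all 2376 lower genes past the threshold but 18 of 18 epithelial genes. The controls differed by -0.38 log2, a shift that is alike for every gene, against an epithelial list median of -2.40. A scaling of that size may account for other genes and is argued against for the epithelial ones. A larger scaling was not tested. Epithelial cells or their RNA are a candidate source among others, although the gate excludes Epcam+ cells and Epcam read 17885 in the Sca1+ reporter-negative samples. The list shares 1 gene with another list, and fibroblasts with less RNA of their own were not tested.

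The smooth muscle list was higher in reporter-high than in reporter-dim cells in mean, with 4 of 16 members past the threshold and its camera call lost with an estimated correlation (adjusted p = 0.789). Fewer epithelial cells alone would raise genes made only by fibroblasts about alike, except dim ones, whose differences are too small. The smooth muscle list rose by 0.59 ± 0.22 (SD, n = 4) more than the adventitial list, in all 4 mice. This argues against fewer epithelial cells as the whole cause only as far as both lists hold such genes. Not all adventitial members rose, Dpp4 standing at -0.68 ± 0.37. Against Sca1+ reporter-negative cells the excess was 0.56 ± 0.59 (SD), in 3 of 4 mice. Of 15 members other than Hhip, 10 (66.7%) were higher in all 4 mice, and Des, Npnt, Ckm, Pcp4 and Synpo2 were not. Smooth muscle cells in the sample and contractile genes in the reporter-high fibroblasts themselves cannot be told apart, since some members are dim and others may be made by both cell types. Gli1 itself differed little between reporter-high and reporter-dim cells (0.17 ± 0.21, adjusted p = 0.73 with limma). The gp38+ gate would remove smooth muscle cells that lack gp38, and 1 member is in another list.

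Genes of interstitial cells of Cajal, and some of glia and pericytes, were higher in Sca1- than in Sca1+ reporter-negative cells, Ano1 reading 16345 against 7749 and Rgs5 32607 against 7195. Of 205 genes lower in Sca1+ cells outside the Cajal list, 86.8% rose with its mean among arrays of the same population, as did 86.3% of 205 with the glial and neuronal list and 84.5% of 206 with the pericyte list, against 39.9%, 40.3% and 41.7% of genes not called. Without the Sca1- array of mouse 1 these fell to 73.7%, 55.6% and 68.9%, so these 3 kinds of cells cannot be told apart as sources; the gp38+ gate would remove such cells where they lack gp38, and these lists share 0 genes with others. Shares of each list's own members, tried first (with the bound for excluding a cell type lowered from 50% to 10% after they were seen), were set aside because those genes define the pattern. The epithelial list differed by -0.025 ± 0.19 (SD, n = 4; higher in 1 of 4 mice), which argues against epithelial content as the cause, and a difference between Sca1- and Sca1+ fibroblasts stays open, untested.

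Regrouping the arrays within mice gave at most 845 genes by the moderated F test in 99 other regroupings against 5522, 1 of 100 being as large. This is the smallest share that 100 can give and lies under 0.05. It rests on the mouse labels, and the arrays of 1 of the 4 mice did not match one another. Shared calls reached 253 or more in 3 of 100, the real one included, a share under 0.05. This regrouping shuffled the 3 Sca1+ populations within mice. A low share therefore shows only that these populations differ, not that reporter-high and reporter-dim cells share a pattern. The 2 other regroupings that reached it gave 476 and 520, more than the real grouping, and what they have in common was not tested. For each pair of populations the 8 splits that part the arrays of each mouse are too few for a share under 0.05 (1 of 8 being as large in each comparison). The real and highest other counts were 5276 and 1 (reporter-high against Sca1+ negative), 258 and 0 (reporter-dim against Sca1+ negative), 242 and 0 (reporter-high against dim), 419 and 0 (by Sca1), 6143 and 0, and 2368 and 0 (reporter-high and dim against Sca1-), all with limma. Over all 35 splits, which also put both arrays of a mouse on one side, the highest others were 1, 1, 0, 223, 3408 and 2736 in this order. In the last, exchanging the reporter-dim array of mouse 3 with the Sca1- array of mouse 1 gave more genes than the real split. That split followed the first principal component, which followed the epithelial list. The arrays on one side read -25.9, -23.6, -1.56 and -0.859 on it, and the others from 7.81 to 47.6. The split with 223 also followed this order, and that with 3408 did not. The cause was not tested.

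In 268 groups of 4 arrays 23 held a value far from the other 3 (log2 signal, mean of the other 3 in brackets); chance sets apart about 1 group in 20. Of these, 15 belong to the reporter-negative arrays of mouse 1. In its Sca1- array Pdpn read 11.92 (10.68), Kcnk1 11.08 (13.27), Pof1b 11.77 (12.52), and the list means were 12.47 (11.67) for Hedgehog targets, 11.75 (11.29) for BMP ligands, 11.49 (10.98) for complement, 13.19 (12.25) for collagens, 12.57 (11.90) for basement membrane, 11.70 (10.89) for matrix proteases, 10.88 (10.43) for PDGFRA-high markers and 10.40 (9.93) for reticular cell markers. In its Sca1+ reporter-negative array Bmp6 read 12.18 (11.29), Itga8 9.16 (8.01), collagens 13.38 (12.90) and basement membrane 12.60 (12.13). The rest were in reporter-positive cells: Ccn2 14.97 (15.29), Kit 8.24 (7.71), lamina propria markers 11.86 (12.10) and interstitial cell of Cajal genes 10.26 (10.02) in the reporter-high array of mouse 3, Bmper 7.32 (7.59) in the reporter-dim one, Prrx1 9.70 (10.16) in reporter-high mouse 2, Wnt ligands 9.38 (9.36) in mouse 1 and retinoid handling 11.25 (11.13) in mouse 4.

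Outside the genes tested, 3294 of 15588 probe sets without a gene passed the threshold with limma between reporter-high and Sca1+ reporter-negative cells. The hybridization controls differed by -0.38 log2 between these populations (exact p = 0.0286, the smallest 4 against 4 arrays can give; lower in reporter-high cells).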

How the results depend on the processing

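Background subtraction, scaling to hybridization controls, the epithelial covariate, the deposited scores, each mouse left out and the block with 2 animals were chosen after the data were seen. Counts below follow the order reporter-high against Sca1+ negative (5276), dim against Sca1+ negative (258), high against dim (242), Sca1+ against Sca1- (419), high against Sca1- (6143), dim against Sca1- (2368), F test (5522) and shared calls (253). Unless a value or the construction is given, the cause was not tested.

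Quantile normalization, centring, the mean of probe sets, the trend with robust variances and the filter on genes above the array median in at least 4 arrays kept all 8 counts within 1.5 times. The array medians were near equal beforehand (662 to 687). Agreement under quantile normalization and centring was therefore largely given in advance and says little. With 1 array of the 2 populations compared left out (any array for the F test, lists and shared calls), high against Sca1+ negative ran from 4118 to 5636, high against Sca1- from 5151 to 6856, the F test from 4464 to 6124 and list calls from 42 to 52, all within 1.5 times. The other counts moved: dim against Sca1+ negative 34 to 1258, high against dim 0 to 523 (with limma, 2160 at an unadjusted p under 0.05 where it was 0), by Sca1 265 to 789, dim against Sca1- 1409 to 4025 and shared calls 34 to 1298. Leaving out the Sca1- array of mouse 1, outside the comparison, gave the highest counts of all for high against Sca1+ negative (5678), dim against Sca1+ negative (1340) and high against dim (833); no array outside a comparison extended the other ranges.

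Pairing by the labels, with mouse as a block, gave 2386 for dim against Sca1+ negative, 1280 for high against dim, 635 by Sca1, 3769 for dim against Sca1- and 2305 shared calls; it kept the other 3 counts within 1.5 times, and all 233 named calls. With the mismatched mouse as 2 animals the block gave 1571, 1875 and 815 for the first 3 of these and 1512 shared calls. Array weights gave 2160, 1283, 684, 3865 and 2096 where the block gave its 5 values.

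Only the 8 arrays compared gave 490 for high against dim, 116 by Sca1 and 1266 for dim against Sca1-. Without mouse 1, dim against Sca1+ negative rose to 1540, high against dim to 620 and shared calls to 1510. Without mouse 2 the 8 counts were 2734, 10, 0 (limma; 2096 at an unadjusted p under 0.05), 155, 3838, 614, 2600 and 10. Without mouse 3, dim against Sca1+ negative and shared calls were 33 each, by Sca1 228 and dim against Sca1- 1529. Without mouse 4 the counts were 3194, 10, 0 (limma; 2006 at an unadjusted p under 0.05), 133, 789 for dim against Sca1-, 3063 and 10 shared.

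Raising dim values to the 25th percentile gave 49, 48 and 49 (dim against Sca1+ negative, high against dim, shared), background subtraction 76, 148 and 75, and the deposited scores 41, 20 and 41, with 270 by Sca1. Testing only genes with a mean above the median gave 370 for high against dim. All probe sets, more features by construction, gave 11812, 420, 1041 by Sca1, 14058, 5246, 12512 and 410. The 2-fold limit, stricter by construction, gave 1230, 66, 134, 191, 1643 and 561. Dividing the control arrays gave 60.5 shared calls, with 2 arrays for each comparison. Camera with an estimated correlation called 4 lists in place of 45.

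Scaling to the hybridization controls gave 11815, 473, 9929 for high against dim, 13375 for high against Sca1-, 11933 and 463 shared. The epithelial covariate gave 1 (1526 at an unadjusted p under 0.05), 39, 0 (limma; 1458 unadjusted), 168 for high against Sca1-, 1287 for dim against Sca1-, 929 and 1 shared; the covariate itself fell by 2.32 between reporter-high and Sca1+ negative arrays, so that it takes up much of that contrast. It reversed 19 differences of named genes between high and Sca1+ negative: Pdpn -0.20, Kcnk1 0.35, Rnf43 0.19, Id3 -0.081, Cxcl12 -0.29, Rsad2 0.47, Mfap4 -0.47, Rarres2 -0.041, Fosl1 0.18, Hspa1b -0.000999, Top2a 0.44, Dpp4 0.075, Ackr4 -0.52, Hapln1 -0.22, Vcam1 -0.062, Gucy1a1 -0.25, Krt18 0.21, Krt7 0.16 and Krt19 0.10.

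Of 290 named differences 233 were called. Their direction held in all other alternatives run, and the threshold was lost by 126 under the epithelial covariate, 119 without mouse 2, 105 without mouse 4, 67 without mouse 3, 8 without mouse 1, 62 with the deposited scores, 59 with the 25th percentile, 51 with 8 arrays, 35 with background subtraction, 13 with hybridization scaling, 6 each with quantile normalization and the mean of probe sets, 3 with the block of 2 animals, and 2 each with centring and the trend. With 1 array left out 386 of these results lost it and 1478 kept it. An offset before the log was not run because the scores are standardized values of signals on a log scale, and the recovered signals reproduced them without one. Signal over background limits dim genes, whose differences are too small.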

Other observations

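The counts of genes set apart in 1 population, and the genes named here, were chosen after the values were seen. Sca1- reporter-negative cells had 162 genes higher than in each of the other 3 populations (204 with mouse as a block), led by Kcna1, at least 3.26 log2 higher than in any other, and with Tmem229a (386, 436 and 552 in the Sca1+ populations in the order high, dim and negative, against 2910) and the neuropeptide-processing enzyme Cpe (1263, 684 and 1181 against 6193). Reporter-high cells had 74 (432 with the block), led by Hhip, with the actin Actc1, the growth factor Pdgfc, Zfp536, Myl9, Mn1 and the basement membrane linker Frem2. Each of the 74 must pass against reporter-dim cells. That comparison called 0 genes with limma without mouse 2 (2096 at an unadjusted p under 0.05), without mouse 4 (2006 unadjusted) or with the epithelial covariate (1458 unadjusted). Sca1+ reporter-negative cells had 30 (42 with the block), with Ptx3 at 1158 and 890 in reporter-high and dim, 366 in Sca1- and 5749 in Sca1+ reporter-negative cells, and with the transcription factor Ebf3 (804, 797 and 589 against 2113) and the matrix protein Sned1 (2983, 3740 and 2404 against 8885).

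Reporter-dim cells had 0 genes higher and 0 lower than in each other population with limma, and 0 and 2 with the block. Genes lower than in each other population numbered 159 in reporter-high, 2 in Sca1+ reporter-negative and 163 in Sca1- cells (791, 29 and 299 with the block). The 159 equal in number all genes lower in reporter-high than in reporter-dim cells, so they rest on that comparison too.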
